A study of Chimonocalamus delicatus with 27 samples.

How the data were processed

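RNA sequencing libraries of Chimonocalamus delicatus were grouped by the labels into a growth stage set (shoot and stems of 0.5, 1, 2 and 3 years, 15 libraries) and a plant part set (leaf, branch, stem and rhizome, 12 libraries), with 3 libraries in each of the 9 groups. The data came as 1 deposited file in which the table of each set stood under a header of its own. The growth stage table held 55972 genes, of which 5036 had MSTRG identifiers, and 57356 genes stood in that of the plant parts, of which 6420 had them. The other 50936 genes, with PH02Gene identifiers, were shared and had the same description in both tables. MSTRG identifiers were specific to a set, since of 506 that occurred in both only 6.5% had the same description. No column of values was left without a sample.

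The expected counts per gene and library were used as the authors deposited them, and 58.7% and 64.5% of the values above 0 were exactly whole as written, with no tolerance, in the growth stage and plant part tables. The FPKM values, which relate fragments to transcript length and library size, were also used as deposited by the authors, per the file headers. The submitters' notes name HISAT2, StringTie 1.3.1 and RSEM without role or order, so which tool made which value is not stated. The genome build is not given in the sources used here. Gene symbols, descriptions, KEGG numbers and transcription factor families were taken from the tables, where 97.7% and 97.8% of the tested genes had a description and 24.8% of them in each set had a KEGG number. The symbols and descriptions are those of similar genes of other species. Genes of 1 family can share reads, and the counting may have split them.

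Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization) in R 4.3.3, with all groups of a set in 1 fit and group as the only factor. No test crossed the sets, since they may be different batches. Genes with an FPKM of 1 or more in at least 3 libraries of the set were tested, 29538 in the growth stage set and 29630 in the plant part set, and 26434 and 27726 were left out. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each of the 8 comparisons, with calls at 0.05. The plan fixed before the data were examined named limma on log2(FPKM + 1) for a table without counts and edgeR for a table with them. As the tables held counts, edgeR was used, and limma 3.58.1 on log2(FPKM + 1) was run as an alternative. Where a group had 0 counts in every library, the fold is a lower bound against a floor of 3 counts over the group.

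The test was tested on simulated counts with 200 changed genes. For the 0.5-year stem against the shoot (29538 genes), edgeR recovered 15% of 2-fold and 80% of 4-fold changes, and 2.1% of its calls were false. For branch against stem (29630 genes) it recovered 1% and 40%, and 2.4% of its calls were false.

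The 17 gene lists were fixed before the data were examined, from KEGG numbers and words in the descriptions. They were terpenoid backbone, terpene synthases, squalene, sterol and triterpene synthesis, gibberellin and labdane diterpenoids, carotenoid and abscisic acid, CYP71, CYP76, CYP99 and CYP701 cytochromes P450, lignin and phenylpropanoid, cellulose synthase and cell wall expansion, flavonoid, jasmonate, light harvesting and photosystem, cell division, starch and sucrose, heat shock, defence, root endodermis and silicon uptake, and cuticle and wax. The flavonoid list took in a vacuolar-sorting receptor through its KEGG number, the lignin list a putrescine hydroxycinnamoyltransferase, and the backbone list a solanesyl-diphosphate synthase and genes described only as hypothetical. Only 19 cell division genes were tested in the plant part set. Lists were tested with camera (limma) at a preset correlation between genes of 0.01, adjusted over the 136 tests, and again with a correlation estimated from the data. With the preset value 46 tests were called, and with the estimated correlation none was, the lowest adjusted p being 0.384.

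The genes named follow a rule fixed before the data were examined. It took called genes with a functional description, a mean FPKM of 10 or more in the higher group and no overlap between the groups, and of these the 5 largest rises and 5 largest falls in log2(FPKM + 1), or 3 and 3 between neighbouring stem ages. To these it added the called member of each list with the largest rise and fall, the most abundant member of each backbone step and the 8 most abundant terpene synthases of each set. The species tag of a description was ignored, and descriptions that were only a clone or locus identifier were passed over. The 6 TPS7 genes that were summed were chosen after their values were seen.

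Also run, as fixed before the data were examined, were limma on log2(FPKM + 0.1), quantile normalization, no expression filter, a mean FPKM of 5 or more, only the 6 libraries compared, all 27 libraries in 1 fit, a replicate block, leaving out each library in turn, RLE size factors, DESeq2 1.42.0, a call that also needed a log2 change of 1, and the estimated correlation. Chosen after seeing the data were limma on log2(FPKM + 1) beside edgeR, leaving out shoot library 3 and 1-year library 1 together, leaving out part-set stem library 1 and rhizome library 2 together, and summing the 0.5-year libraries to 1 sample. Pairs of replicates were compared by chi-square over genes with a summed count of 20 or more. The 0.5-year libraries were kept as 3 in the main tests. They differed by more than sampling noise, but library preparation adds spread, so this does not show separate replicates. Tables were read with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.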

Results

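The series measured gene expression by RNA sequencing in Chimonocalamus delicatus, a fragrant bamboo, to ask how terpenoid genes differ with the age of the culm (the bamboo stem) and with the part of the plant. It held 27 libraries in 9 groups of 3. The growth stage set covered the shoot and stems of 0.5, 1, 2 and 3 years (15 libraries), and the plant part set covered leaf, branch, stem and rhizome (12 libraries). The labels give no age for the stem of the part set, which is called the part-set stem here. Totals of the deposited expected counts were 8615092 to 12422327 per library in the growth stage set and 6257623 to 9010973 in the plant part set, with 32571 to 37303 and 32704 to 36272 genes above 0. A gene with 0 counts was therefore below 0.242 to 0.348 and below 0.333 to 0.479 CPM (counts scaled to the library total) per library, the level of 3 counts, and such floors cover counting error only. The labels do not say that the 3 replicates of a group came from separate plants, so p-values measure the spread between these libraries, which may be technical. Where some members of a list were at 0 in every library of a group or at or under the floor in both, the median is also given "at the bound", with the former at their bound and without the latter. Levels are mean FPKM ± SD with n = 3, log2 changes are edgeR estimates with their standard error (SE), and adjusted p is from edgeR for genes and from camera for gene lists.

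The spread between replicates differed among the groups. The biological coefficient of variation was 5.43% in the 0.5-year stem, against 24.3% to 44.2% in the other stages. Counts of each pair of 0.5-year libraries differed by 1.78 to 2.48 in chi-square per degree of freedom, against 13.08 to 51.09 for pairs in the other stages. In the plant part set the coefficient of variation was 19.9% in leaf, 30.8% in branch, 39.4% in the part-set stem and 59.9% in rhizome, where libraries 2 and 3 correlated at r = 0.745 across genes, which are not independent replicates.

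**Figure D1:**
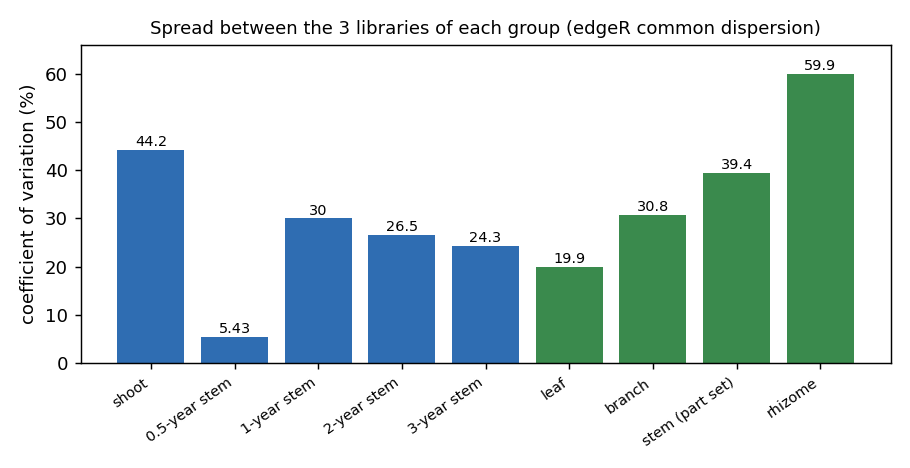
Bars give the coefficient of variation (%) between the 3 libraries of each group, from edgeR's common dispersion, with the growth stage set in blue and the plant part set in green. The 0.5-year stem stands at 5.43% and the rhizome at 59.9%.

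The comparison of the 0.5-year stem with the shoot asked how a young stem differs from a shoot. TPS7 (PH02Gene09152), described as an (E)-nerolidol synthase, rose from 0.433 ± 0.733 to 270 ± 15.3 FPKM (log2 change 9.65 ± 0.95, adjusted p = 6.27e-06). Another TPS7 gene (PH02Gene26515) rose from 0.472 ± 0.694 to 290 ± 15.3 FPKM (9.62 ± 0.83, adjusted p = 7.23e-07), and a further one (PH02Gene09155) rose to 217 ± 5.8 FPKM (7.96 ± 0.98, adjusted p = 1.55e-05). The (-)-germacrene D synthase TPS2 (PH02Gene40249) rose from 6.44 ± 9.1 to 55.2 ± 1.7 FPKM (3.53 ± 0.80, adjusted p = 0.00197). TPS26 (PH02Gene44577), described as an (S)-beta-macrocarpene synthase, fell from 1.71 ± 0.35 to 0.0667 ± 0.0732 FPKM (-4.21 ± 1.34, adjusted p = 0.0158), a call that ended without 0.5-year library 1 (adjusted p = 0.0554) or 2 (0.0562) and after quantile normalization (0.101). Of 22 terpene synthases tested, 14 rose and 1 fell, and 15 and 1 when adjusted over the list alone. Their median log2 change was 3.04 (camera, adjusted p = 0.000144, and adjusted p = 0.647 with an estimated correlation). Shoot library 3 stood apart from the other shoot libraries. In it, 9.07% of the genes at 5 FPKM or more in at least 1 shoot library lay over 2-fold above both others. Its summed terpene synthase FPKM was 106 against 20.5 and 14.6 in shoot libraries 1 and 2, and without it the list median was 5.78 (adjusted p = 5.14e-07). The TPS7 genes share a symbol and may share reads, so the split between them is uncertain.

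Upstream of the synthases, farnesyl pyrophosphate synthase FPS (PH02Gene06534), which makes the precursor of sesquiterpenes, rose from 43.2 ± 24 to 277 ± 9.4 FPKM (3.05 ± 0.37, adjusted p = 1.36e-05). Geranylgeranyl pyrophosphate synthase GGPPS1 (PH02Gene08799) rose from 0.123 ± 0.214 to 23.1 ± 2.56 FPKM (7.60 ± 0.74, adjusted p = 1.98e-06). In the plastid pathway, DXR (PH02Gene19646) rose by 1.67 ± 0.26 on the log2 scale (adjusted p = 9.88e-05) and the HDS gene ISPG (PH02Gene14026) by 2.12 ± 0.28 (adjusted p = 2.81e-05). In the mevalonate pathway, HMGS (PH02Gene21584) rose from 38.5 ± 18 to 63.1 ± 0.72 FPKM (1.09 ± 0.24, adjusted p = 0.00177). HMGR (PH02Gene25183), the rate-limiting enzyme of that pathway, fell from 51.2 ± 3.5 to 15.8 ± 0.19 FPKM (-1.33 ± 0.38, adjusted p = 0.00907) and MVD2 (PH02Gene06879) from 22.9 ± 6.35 to 4.59 ± 0.584 FPKM (-1.97 ± 0.31, adjusted p = 0.000125). The more abundant MVD2 gene PH02Gene20453 was not called, at 28.6 ± 6.6 and 15.8 ± 0.99 FPKM (-0.51 ± 0.21, adjusted p = 0.0588). It was called lower without shoot library 3 (adjusted p = 0.00591), also with 1-year library 1 left out, with RLE size factors, DESeq2 and limma, after quantile normalization and at a mean FPKM of 5 or more. Of the most abundant gene of each step, 1 of 6 in the mevalonate pathway rose and 3 fell, and 4 of 7 in the plastid pathway rose and 0 fell. Over the whole terpenoid backbone, 21 of 53 genes rose and 8 fell, with the same counts adjusted over the list alone, a median log2 change of 0.56, or 0.53 at the bound, and no call (adjusted p = 0.0936).

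The cell-wall loosening expansin EXPB3 (PH02Gene02936) fell from 262 ± 84.8 to 0.191 ± 0.0466 FPKM (-10.03 ± 0.46, adjusted p = 4.78e-09) and the replication helicase subunit MCM4 (PH02Gene12916) from 43.4 ± 35.8 to 0.0573 ± 0.0232 FPKM (-9.12 ± 0.73, adjusted p = 4.16e-07). Of 33 cell division genes 20 fell and 1 rose (23 and 1 adjusted over the list alone). The median was -3.19 (adjusted p = 3.49e-05, and adjusted p = 0.647 with an estimated correlation). Of 71 genes of cellulose synthase and wall expansion 44 fell and 14 rose (44 and 14 adjusted over the list alone). The median was -1.77 (adjusted p = 1.25e-05, and adjusted p = 0.481 with an estimated correlation), and the list call ended at a mean FPKM of 5 or more (0.08, 0.218). Among those that rose, the COBRA-like gene BC1L6 (PH02Gene20375) went from 7.3 ± 5.81 to 217 ± 0.187 FPKM (5.29 ± 0.62, adjusted p = 1e-05). Of 38 cuticle and wax genes 18 fell and 5 rose (19 and 5 adjusted over the list alone). The median was -1.44 (adjusted p = 0.0163, and adjusted p = 0.744 with an estimated correlation). That call ended without shoot library 3 (-0.79, 0.262), with limma, after quantile normalization, with all 27 libraries in the fit and at a mean FPKM of 5 or more, where the median was 0.12. Among them GL1-4 (PH02Gene27008) fell from 69.1 ± 9.05 to 0.124 ± 0.052 FPKM, and KCS11 (PH02Gene21017) rose from 0.666 ± 0.683 to 17.7 ± 0.482 FPKM. Other large falls were BGLU28 (PH02Gene47638), SIK1 (PH02Gene13033), MGS1 (PH02Gene37817) and At1g77060 (PH02Gene15659), with log2 changes of -9.37, -8.64, -7.40 and -7.84.

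ERF109 (PH02Gene23495), an ethylene-responsive transcription factor, rose from 0.503 ± 0.291 to 246 ± 9.75 FPKM (9.27 ± 0.46, adjusted p = 7.86e-09). Both genes described as early nodulin-93 (PH02Gene12978 and PH02Gene12976) and the benzoquinol hydroxylase homologue PH02Gene24034 rose to 923 ± 30.9, 492 ± 14.1 and 295 ± 43 FPKM, from 2.05 ± 0.744, 3.31 ± 2.92 and 1.96 ± 2.26. Of 60 jasmonate genes 40 rose and 10 fell (40 and 11 adjusted over the list alone). The median was 2.22, or 2.17 at the bound (adjusted p = 1.45e-09, and adjusted p = 0.523 with an estimated correlation). TIFY11F (PH02Gene09510), of the family of jasmonate response repressors, rose from 0.296 ± 0.158 to 80.4 ± 6.14 FPKM, whereas the lipoxygenase LOX2.3 (PH02Gene44707) fell from 11.9 ± 10.9 to 0.009 ± 0.0156 FPKM. Of 42 carotenoid and abscisic acid genes 21 rose and 1 fell (21 and 1 adjusted over the list alone). The median was 0.95, or 0.98 at the bound (adjusted p = 0.00397, and adjusted p = 0.734 with an estimated correlation). Without shoot library 2 or 3 it was 0.58 or 1.45 (adjusted p = 0.0187 or 0.000370). NCED4 (PH02Gene08292) of abscisic acid synthesis was at 144 ± 10.8 against 1.62 ± 0.33 FPKM. Of 75 heat shock genes 48 rose and 5 fell (48 and 5 adjusted over the list alone). The median was 2.52 (adjusted p = 1.03e-06, and adjusted p = 0.629 with an estimated correlation). The small heat shock gene HSP24.1 (PH02Gene06505) rose from 0.37 ± 0.267 to 108 ± 8.82 FPKM and HSP70 (PH02Gene42525) fell from 15.3 ± 7.7 to 0.861 ± 0.243 FPKM. The summed FPKM of the heat shock list was 8844 to 9213 in the 0.5-year libraries against 2198 to 4179 in those of the other stages.

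Of 63 light harvesting genes 14 rose and 10 fell (9 and 8 adjusted over the list alone), with no list call (median 0.80, adjusted p = 0.343). Their summed FPKM was 2652 in shoot library 3 against 943 and 523 in shoot libraries 1 and 2, and without library 3 the list was called higher (1.49, adjusted p = 0.00357).

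In all, edgeR called 15891 of 29538 genes, 7818 higher and 8073 lower. With limma on log2(FPKM + 1), where the median change of all genes was -0.28, 6140 were higher and 11502 lower, so that 34.8% and not 49.2% of the calls were higher. With the 3 close 0.5-year libraries summed to 1 sample, a setting chosen after seeing the data in which the lone sample is assumed to vary like the other groups, 9418 genes were called, and HMGR (PH02Gene25183) and TPS26 (PH02Gene44577) were not among them. The TPS26 call also ended after quantile normalization.

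**Figure D2:**
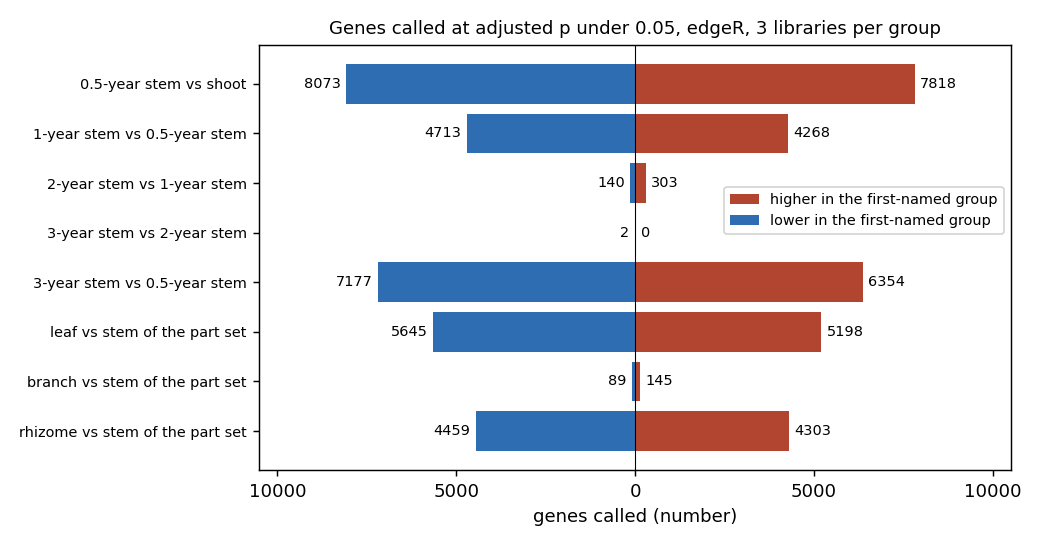
Bars give the number of genes called by edgeR at an adjusted p under 0.05 in each of the 8 comparisons, to the right those higher and to the left those lower in the first-named group. The 2-year against 1-year and the branch comparisons called 443 and 234 genes, and the 3-year against 2-year comparison called 2.

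The comparison of the 1-year with the 0.5-year stem covered the first change of age. The (E)-nerolidol synthase gene TPS7 (PH02Gene09152) fell from 270 ± 15.3 to 1.22 ± 0.78 FPKM (-7.84 ± 0.86, adjusted p = 8.53e-05), PH02Gene26515 to 2.24 ± 1.1 FPKM (-7.09 ± 0.72, adjusted p = 2.62e-05) and PH02Gene09155 to 1.73 ± 0.15 FPKM (-7.00 ± 0.93, adjusted p = 0.000165). The TPS7 gene PH02Gene05612 was not called, at 51.5 ± 3.1 and 38.9 ± 21 FPKM (-0.48 ± 0.63, adjusted p = 0.593). Isopentenyl diphosphate isomerase IPI1 (PH02Gene44781), which interconverts the C5 units, fell from 42.7 ± 2.1 to 10.2 ± 3.7 FPKM (-2.10 ± 0.31, adjusted p = 0.000304), and GGPPS1 (PH02Gene08799) from 23.1 ± 2.56 to 2.53 ± 1.49 FPKM. Of 22 terpene synthases 7 fell and 1 rose, also when adjusted over the list alone, and the median was -0.44 (adjusted p = 0.00538, and adjusted p = 0.744 with an estimated correlation). The list call ended without the expression filter (adjusted p = 0.0710) and with all 27 libraries in the fit (0.103), and without 1-year library 3 the median was -1.11 (adjusted p = 0.00308). Of 53 backbone genes 7 rose and 13 fell (8 and 14 adjusted over the list alone), with no call (median -0.12, adjusted p = 0.407). DXR (PH02Gene19646) rose from 31.5 ± 2.7 to 81.9 ± 23 FPKM (1.31 ± 0.25, adjusted p = 0.00168). The GPPS-step gene SPS1 (PH02Gene03163) rose from 10.6 ± 0.85 to 18.5 ± 1.4 FPKM (0.75 ± 0.15, adjusted p = 0.00206). SPS1 was placed at that step by its KEGG number, and the data do not show which product it makes. HDR (ISPH, PH02Gene06218) rose from 58.5 ± 2.7 to 135 ± 57 FPKM (1.14 ± 0.37, adjusted p = 0.0296), a call that ended without 1-year library 2 (0.145), without 0.5-year library 1 (0.0806), 2 (0.0734) or 3 (0.0818), and after quantile normalization. GGPS (PH02Gene17903) rose from 23.7 ± 3.4 to 62.3 ± 12.7 FPKM (1.34 ± 0.42, adjusted p = 0.0275). The GGPS call ended without 1-year library 2 (adjusted p = 0.0503) or 3 (0.0790) and without 0.5-year library 1 (0.0760), 2 (0.0588) or 3 (0.0934), and with limma on log2(FPKM + 0.1).

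Of 133 lignin and phenylpropanoid genes 55 fell and 11 rose (58 and 12 adjusted over the list alone). The median was -0.88, or -0.89 at the bound (adjusted p = 1.33e-05, and adjusted p = 0.638 with an estimated correlation). The laccase LAC11 (PH02Gene48239) fell from 28.2 ± 2.54 to 0.231 ± 0.164 FPKM. Of 71 wall expansion genes 17 fell and 3 rose, also when adjusted over the list alone (median -0.69, or -1.14 at the bound, adjusted p = 0.0181, and adjusted p = 0.647 with an estimated correlation), with XTH8 (PH02Gene38858) at 0.376 ± 0.0824 against 17.6 ± 1.88 FPKM. That list call ended without the filter (0.0964) and with all 27 libraries (0.108), and without 0.5-year library 3 the median was -0.37 (adjusted p = 0.0213). Of 63 light harvesting and photosystem genes 30 fell and 1 rose (32 and 1 adjusted over the list alone). The median was -1.53 (adjusted p = 4.72e-08, and adjusted p = 0.647 with an estimated correlation). CAB2R (PH02Gene49412) fell from 45.6 ± 6.91 to 0.549 ± 0.599 FPKM. Of 75 heat shock genes 43 fell and 1 rose (48 and 3 adjusted over the list alone). The median was -1.50, or -1.54 at the bound (adjusted p = 1.35e-10, and adjusted p = 0.473 with an estimated correlation), and -2.32 without 1-year library 1 (adjusted p = 4.47e-21). HSP24.1 (PH02Gene06505) fell from 108 ± 8.82 to 5.75 ± 5.58 FPKM. Of 58 defence genes 19 fell and 2 rose (19 and 3 adjusted over the list alone). The median was -0.93, or -0.74 at the bound (adjusted p = 0.0115, and adjusted p = 0.629 with an estimated correlation), a call that ended without 1-year library 1 (0.0961), without the filter (0.195) and with all 27 libraries (0.0664). The chitinase Cht7 (PH02Gene32087) fell from 135 ± 14.8 to 3.01 ± 1.43 FPKM. Of 38 cuticle and wax genes 11 fell and 2 rose (13 and 2 adjusted over the list alone). The median was -1.79, or -2.20 at the bound (adjusted p = 0.00814, and adjusted p = 0.662 with an estimated correlation), among them KCS20 (PH02Gene44899) at 0.116 ± 0.12 against 3.58 ± 0.159 FPKM. At a mean FPKM of 5 or more the cuticle test pointed higher, with no call (median 0.70, adjusted p = 0.495).

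Among the rises named by rule were those of NAM-B1 (PH02Gene19280), a NAC transcription factor, from 0.189 ± 0.146 to 53 ± 15.7 FPKM (8.08 ± 0.49, adjusted p = 3.95e-06), the potassium transporter HAK1 (PH02Gene08939), from 0.834 ± 0.205 to 94.6 ± 78 FPKM (6.73 ± 1.2, adjusted p = 0.00108), and At2g25737 (PH02Gene40465), from 1.49 ± 0.295 to 93.8 ± 55.9 FPKM. CBL9 (PH02Gene50536) and the isoflavone reductase homologue IRL (PH02Gene36096) fell from 243 ± 3.8 to 0.928 ± 0.174 and from 281 ± 17.5 to 4.75 ± 3.55 FPKM. edgeR called 8981 genes, 4268 higher and 4713 lower. With the 0.5-year libraries summed to 1 sample, HAK1, GGPS (PH02Gene17903), DXR (PH02Gene19646), SPS1 (PH02Gene03163) and HDR (PH02Gene06218) were no longer called.

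The comparison of the 2-year with the 1-year stem covered the next step of age. RGLG1 (PH02Gene49137), a ubiquitin ligase, rose from 11.2 ± 3.2 to 62.7 ± 16.7 FPKM (2.69 ± 0.36, adjusted p = 0.0104). A gene described as WRKY transcription factor 19 (MSTRG.36940) rose from 60.5 ± 28.9 to 300 ± 78.3 FPKM (2.49 ± 0.36, adjusted p = 0.0137) and an abscisic stress-ripening gene (PH02Gene20470) from 51.6 ± 17.9 to 249 ± 103 FPKM (2.48 ± 0.43, adjusted p = 0.0218). The disease resistance gene MSTRG.48001 was at 0 in all 3 libraries of the 2-year stem and at 16.3 ± 5.91 FPKM in the 1-year stem, at least 77.1-fold lower (adjusted p = 0.0494). The heat shock gene HSP16.9A (PH02Gene22221) fell from 15.9 ± 12.9 to 0.934 ± 1.2 FPKM (adjusted p = 0.0390) and the chlorophyll-binding gene CAB-M9 (PH02Gene04237) from 10.5 ± 3.27 to 0.883 ± 1.08 FPKM (adjusted p = 0.0405). TIFY11A (PH02Gene42410) rose from 15.9 ± 2.1 to 54.1 ± 18.9 FPKM (adjusted p = 0.0171) and the wax gene CER26L (PH02Gene01752) from 0.463 ± 0.165 to 4.28 ± 0.726 FPKM (adjusted p = 0.0307). Except for RGLG1, each of these 8 genes lost its call without at least 1 library. Without 1-year library 1, 2 or 3, the calls of 4, 7 and 2 of them ended, with adjusted p of 0.0665 to 0.0943, 0.0519 to 0.111 and 0.0584 to 0.0618. Without 2-year library 1, 2 or 3, those of 5, 1 and 7 ended, with adjusted p of 0.0542 to 0.121, 0.0619 and 0.0550 to 0.201.

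No terpene synthase was called (0 of 22 by edgeR, also when adjusted over the list alone), but the list as a whole was called lower, with a median of -1.02 (adjusted p = 0.0244, and adjusted p = 0.821 with an estimated correlation). That call ended without 1-year library 3 (median -0.47, adjusted p = 0.132) and without 2-year library 1 (-0.81, 0.160) or 3 (-0.86, 0.0653), with limma, without the filter, at a mean FPKM of 5 or more and with all 27 libraries in the fit. The backbone had 0 of 53 genes called, also over the list alone, and no list call (median -0.14, or -0.13 at the bound, adjusted p = 0.473). Of 63 light harvesting genes 6 fell and none rose (17 and 0 adjusted over the list alone). The median was -1.47, or -1.48 at the bound (adjusted p = 7.18e-16, and adjusted p = 0.629 with an estimated correlation). Of 75 heat shock genes 3 fell and none rose (19 and 1 adjusted over the list alone). The median was -0.82, or -0.72 at the bound (adjusted p = 8.49e-05, and adjusted p = 0.647 with an estimated correlation), and the call ended without 1-year library 1 (-0.16, 0.0542). The lists of jasmonate genes (2 of 60 rose, 6 adjusted over the list alone, median 0.30, or 0.37 at the bound, adjusted p = 0.000117, and adjusted p = 0.647 with an estimated correlation) and cuticle and wax genes (2 of 38 rose, 8 adjusted over the list alone, median 0.67, or 1.39 at the bound, adjusted p = 0.000136, and adjusted p = 0.638 with an estimated correlation) were called higher. The jasmonate median was 0.46 without 1-year library 3 and 0.19 without 2-year library 3 (adjusted p = 1.05e-05 and 0.00122), and that of cuticle and wax was 1.15 without 1-year library 3 and 0.37 without 2-year library 2 (8.75e-05 and 0.00360). The cuticle call ended at a mean FPKM of 5 or more (0.495). In all 443 genes were called, 303 higher (68.4%) and 140 lower. With limma on log2(FPKM + 1), where the median change of all genes was -0.16, 271 (33.2%) were higher and 545 lower. Without 1-year library 1, 2 or 3 edgeR called 158, 29 and 250. Without 2-year library 1, 2 or 3 it called 81, 1047 and 15. With the 0.5-year libraries summed to 1 sample, which changes the shared estimate of the spread, 1 gene was called, none of the 8 named. The calls of CAB-M9 (PH02Gene04237), HSP16.9A (PH02Gene22221) and PH02Gene20470 also ended with only the 2 groups or with all 27 libraries in the fit, those of TIFY11A (PH02Gene42410) and CER26L (PH02Gene01752) with all 27, and that of CAB-M9 after quantile normalization.

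The comparison of the 3-year with the 2-year stem called 2 genes, both lower. PIX7 (PH02Gene12712), a receptor-like kinase, fell from 14.7 ± 2.09 to 5.29 ± 0.851 FPKM (-1.46 ± 0.17, adjusted p = 0.0167), and the auxin response factor ARF17 (PH02Gene03160) from 53.8 ± 0.999 to 21.8 ± 3.07 FPKM (-1.29 ± 0.18, adjusted p = 0.0494). The call of ARF17 ended without each of the 6 libraries in turn and that of PIX7 without each of them except 3-year library 1. The adjusted p-values of the lost calls were 0.0978 to 0.135, 0.127 to 0.170 and 0.0803 to 0.197 without 2-year library 1, 2 and 3, and 0.282, 0.0868 to 0.230 and 0.0836 without 3-year library 1, 2 and 3. At an unadjusted p under 0.05 there were 2079 genes, DESeq2 called 91 (25 higher and 66 lower) and limma on log2(FPKM + 1) called 7 (4 higher and 3 lower). The number called was 0 without 2-year library 1, 2 or 3 or without 3-year library 3, and 1 without 3-year library 1. With only the 2 groups or all 27 libraries in the fit, or with the 0.5-year libraries summed to 1 sample, it was 0, and with RLE size factors the call of ARF17 ended. No terpene synthase (0 of 22) and no backbone gene (0 of 53) was called by edgeR, also when adjusted over each list alone, with medians of -0.36 (adjusted p = 0.269) and 0.11 (adjusted p = 0.269). Without 2-year library 2 the backbone list was called higher (median 0.29, adjusted p = 0.00530). The lists of wall expansion (median -0.04, or -0.41 at the bound, adjusted p = 0.0133, and adjusted p = 0.647 with an estimated correlation) and light harvesting (median -0.41, or -0.42 at the bound, adjusted p = 0.0163, and adjusted p = 0.922 with an estimated correlation) were called lower, with 0 of 71 and 0 of 63 genes called and 1 and 0 adjusted over the list alone. Both calls ended with limma on log2(FPKM + 1) and after quantile normalization. The wall expansion call also ended without the filter, with only the 2 groups or all 27 libraries in the fit, and without library 2 of the 2-year (0.376) or 3-year stem (0.0753), its median ranging from -0.09 to 0 with 1 library left out. That of light harvesting ended without 2-year library 1 (0.101) or 3 (0.0829) or 3-year library 3 (0.481).

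The comparison of the 3-year with the 0.5-year stem spanned the ages sampled. The (E)-nerolidol synthase gene TPS7 (PH02Gene09152) was at 0 in all 3 libraries of the 3-year stem, at least 1860-fold lower than in the 0.5-year stem (adjusted p = 1.42e-05), the floor being 3 counts over the group. The TPS7 genes PH02Gene26515 and PH02Gene09155 fell to 0.978 ± 0.85 and 1.01 ± 0.99 FPKM (-7.97 ± 0.76, adjusted p = 5.62e-06 and -7.52 ± 0.97, adjusted p = 4.26e-05). TPS2 (PH02Gene40249) fell from 55.2 ± 1.7 to 9.66 ± 3.3 FPKM (-2.37 ± 0.76, adjusted p = 0.0201), a call that ended without 3-year library 1 (adjusted p = 0.0633) or 3 (0.0762). TPS26 (PH02Gene44577) rose from 0.0667 ± 0.0732 to 1.25 ± 0.332 FPKM (4.28 ± 1.35, adjusted p = 0.0185), a call that ended without 0.5-year library 1 (adjusted p = 0.0623) or 2 (0.0629) and with limma on log2(FPKM + 1). Of 22 terpene synthases 12 fell and 1 rose, also when adjusted over the list alone. The median was -2.13 (adjusted p = 0.000563, and adjusted p = 0.647 with an estimated correlation). The TPS7 gene PH02Gene05612, described as an (S)-beta-bisabolene synthase, was not called, at 51.5 ± 3.1 and 30.8 ± 22 FPKM in the 0.5-year and 3-year stem (-0.55 ± 0.63, adjusted p = 0.496).

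Of the precursor genes, DXS (CLA1, PH02Gene22727), the first step of the plastid pathway, rose from 8.81 ± 0.681 to 67.7 ± 4.66 FPKM (3.10 ± 0.47, adjusted p = 0.000158), and GGPS (PH02Gene17903) from 23.7 ± 3.4 to 100 ± 19 FPKM (2.24 ± 0.43, adjusted p = 0.000849). FPS (PH02Gene06534) was at 277 ± 9.4 and 457 ± 32 FPKM (0.89 ± 0.34, adjusted p = 0.0475), a call that ended without any 1 of the 6 libraries: 0.0960, 0.0545 and 0.105 without 3-year library 1, 2 and 3, and 0.104, 0.0986 and 0.107 without 0.5-year library 1, 2 and 3. It also ended with limma, quantile normalization and the stricter expression filter. The isomerase IPI1 (PH02Gene44781) fell from 42.7 ± 2.1 to 4.48 ± 2.1 FPKM (-3.11 ± 0.32, adjusted p = 1.04e-05) and GGPPS1 (PH02Gene08799) from 23.1 ± 2.56 to 0.412 ± 0.189 FPKM (-5.60 ± 0.65, adjusted p = 1.99e-05). Of the most abundant gene of each step, 0 of 6 in the mevalonate pathway rose and 1 fell, and 4 of 7 in the plastid pathway rose and 1 fell. Over the backbone 12 of 53 rose and 17 fell, also when adjusted over the list alone, with no list call (median -0.20, adjusted p = 0.540).

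The cellulose synthase CESA9 (PH02Gene25266) fell from 209 ± 7.75 to 0.282 ± 0.0717 FPKM (-9.37 ± 1.67, adjusted p = 0.000481), FLA11 (PH02Gene44669) from 229 ± 11.8 to 0.207 ± 0.184 FPKM and PAL (PH02Gene08453), the entry enzyme of phenylpropanoid synthesis, from 368 ± 19.2 to 1.85 ± 2.47 FPKM. The isoflavone reductase homologues IRL (PH02Gene36096 and PH02Gene27584) fell from 281 ± 17.5 and 258 ± 9.24 to 0.166 ± 0.188 and 0.601 ± 0.291 FPKM. Of 133 lignin and phenylpropanoid genes 60 fell and 22 rose, also when adjusted over the list alone (median -0.70, or -0.76 at the bound, adjusted p = 0.00425, and adjusted p = 0.695 with an estimated correlation), a call that ended without the filter (-0.18, 0.0599) and with all 27 libraries in the fit (0.0693). CCR1 (PH02Gene01698) rose from 1.33 ± 0.309 to 20.9 ± 4.59 FPKM. Of 71 wall expansion genes 23 fell and 3 rose, also when adjusted over the list alone (median -0.49, or -1.10 at the bound, adjusted p = 0.0244, and adjusted p = 0.647 with an estimated correlation). That call ended with limma on log2(FPKM + 1) (0.0551), without the filter (0.115) and with all 27 libraries (0.111), and without 0.5-year library 1 the median was -0.30 (adjusted p = 0.0251). XTH (PH02Gene43877) rose from 10.4 ± 1.84 to 99.5 ± 57.4 FPKM. Of 63 light harvesting genes 55 fell and 2 rose (57 and 2 adjusted over the list alone). The median was -3.36 (adjusted p = 5.66e-15, and adjusted p = 0.629 with an estimated correlation). PSBR (PH02Gene08265) fell from 146 ± 5.97 to 0.646 ± 0.439 FPKM and At4g08330 (PH02Gene19244) rose from 1.16 ± 0.183 to 5.5 ± 0.799 FPKM. Of 75 heat shock genes 48 fell and 1 rose (49 and 2 adjusted over the list alone). The median was -2.39, or -2.26 at the bound (adjusted p = 1.33e-10, and adjusted p = 0.481 with an estimated correlation). HSP16.9A (PH02Gene22221) fell from 130 ± 11.9 to 0.407 ± 0.366 FPKM and Dnajb5 (PH02Gene30948) rose from 12.3 ± 0.835 to 16.3 ± 0.505 FPKM.

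Rises named by rule were those of NAM-B1 (PH02Gene19280), to 91.5 ± 8.39 FPKM (9.09 ± 0.50, adjusted p = 4.03e-07), the flavanone 3-dioxygenase F3H-2 (PH02Gene00618), from 0.0707 ± 0.0613 to 88.8 ± 52.6 FPKM (10.32 ± 0.87, adjusted p = 2.36e-06), the ethylene-forming oxidase ACO (PH02Gene02494), from 1.28 ± 0.415 to 144 ± 75.7 FPKM, NAC071 (PH02Gene33943), from 0.884 ± 0.459 to 94 ± 12.3 FPKM, and the lipoxygenase CM-LOX2 (PH02Gene47636), from 0.962 ± 0.235 to 104 ± 39.1 FPKM. NCED3 (PH02Gene40492) of abscisic acid synthesis rose from 8.19 ± 0.701 to 93.1 ± 15.7 FPKM and the endochitinase Cht2 (PH02Gene16703) from 15.1 ± 1.29 to 233 ± 13.4 FPKM. edgeR called 13531 genes, 6354 higher and 7177 lower. With limma on log2(FPKM + 1), where the median change of all genes was -0.13, 5011 were higher and 8203 lower. After quantile normalization, where it was 0.04, 6972 were higher and 6175 lower. With the 0.5-year libraries summed to 1 sample 6690 were called, and TPS2 (PH02Gene40249), TPS26 (PH02Gene44577), FPS (PH02Gene06534) and Dnajb5 were not among them.

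**Figure D3:**
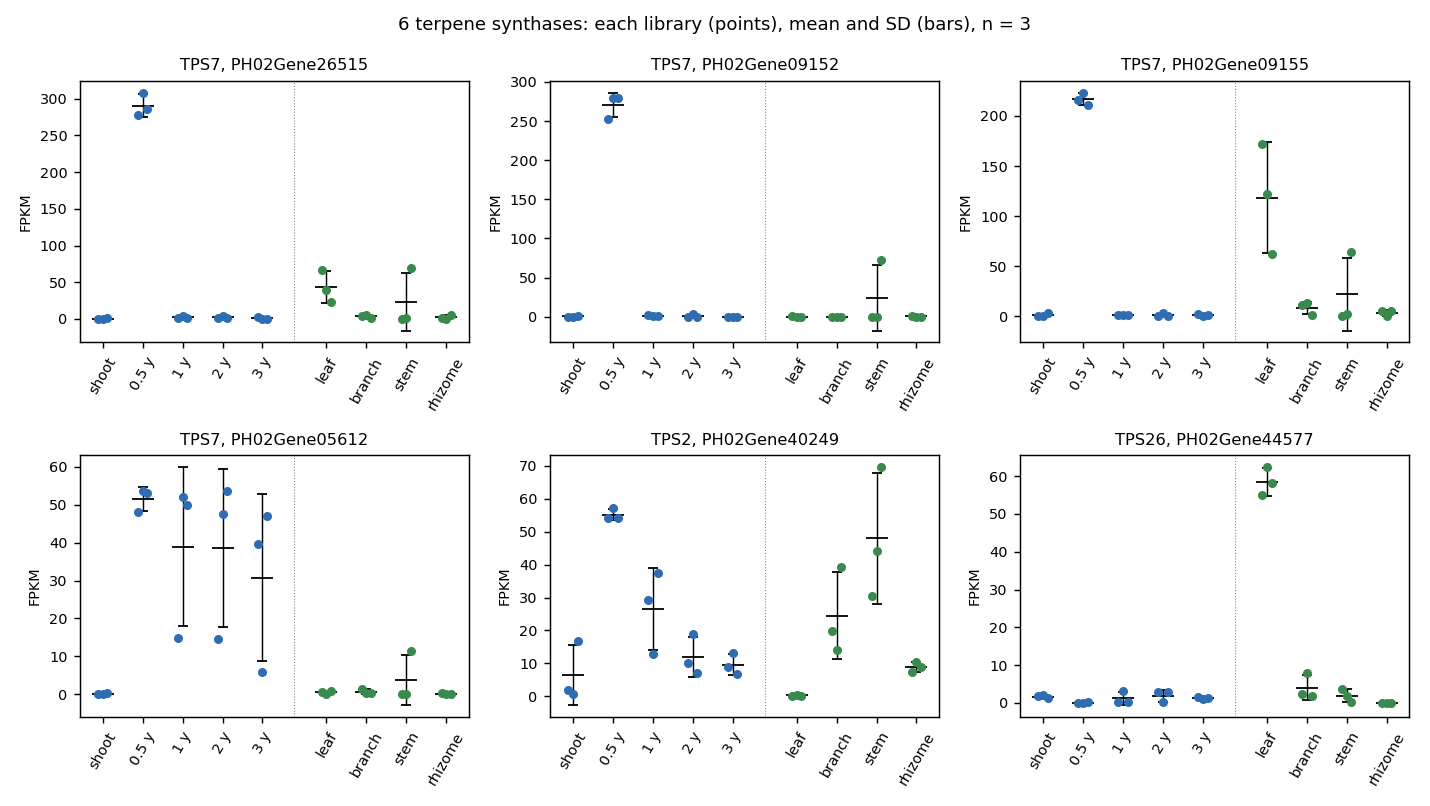
Points give the FPKM of 6 terpene synthase genes in each library, with the mean and SD (n = 3) as bars, for the growth stage set (blue) and the plant part set (green). TPS7 genes PH02Gene26515, PH02Gene09152 and PH02Gene09155 stand at 290, 270 and 217 FPKM in the 0.5-year stem, TPS26 (PH02Gene44577) at 58.5 FPKM in leaf, and the lower ends of some SD bars pass below 0.

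The comparison of leaf with the part-set stem asked how terpenoid genes differ between parts. The germacrene D synthase TPS2 (PH02Gene40249) was at 0.281 ± 0.22 in leaf and 48.1 ± 19.9 FPKM in stem (-7.31 ± 0.65, adjusted p = 1.78e-05), and MSTRG.59063, of the same symbol, at 0.745 ± 0.47 and 60.1 ± 19 FPKM (-6.18 ± 0.55, adjusted p = 1.86e-05). PH02Gene48180, also described as a germacrene D synthase, and the alpha-terpineol synthase homologue TPS10 (MSTRG.17598) were at 0 in all leaf libraries, at least 187-fold (adjusted p = 8.61e-05) and at least 166-fold (adjusted p = 0.00132) lower. TPS26 (PH02Gene44577) was higher in leaf, at 58.5 ± 3.71 against 1.9 ± 1.74 FPKM (5.01 ± 0.86, adjusted p = 0.00187). Of 23 terpene synthases 12 were lower and 2 higher, also when adjusted over the list alone. The median was -6.18, or -3.92 with the 4 members that were all 0 in a group at their bound (adjusted p = 0.00328, and adjusted p = 0.647 with an estimated correlation). The list call ended with limma on log2(FPKM + 1), with all 27 libraries in the fit and without the expression filter, where the median was 0.13. The TPS7 genes PH02Gene09155 and PH02Gene26515 were at 119 ± 55 and 43.3 ± 22 FPKM in leaf and 22.1 ± 36 and 23.4 ± 39 FPKM in stem, with no call (adjusted p = 0.201 and 0.640). Without library 3 of the part-set stem both were called higher in leaf (log2 change 6.79, adjusted p = 0.00674 and 5.93, adjusted p = 0.00858). PH02Gene09155 was also called higher in leaf with limma on log2(FPKM + 1) (adjusted p = 0.0241) and after quantile normalization (0.0180). Summed over 6 TPS7 genes (PH02Gene09149, PH02Gene09151, PH02Gene09152, PH02Gene09155, PH02Gene26515 and PH02Gene50914), chosen after their values were seen, that library had 283 FPKM against 1.63 and 4.73 in stem libraries 1 and 2.

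Of the plastid pathway, HDR (ISPH, PH02Gene06218) was at 310 ± 9.8 against 63.5 ± 10 FPKM (2.37 ± 0.30, adjusted p = 0.000146) and HDS (ISPG, PH02Gene14026) at 201 ± 14 against 82 ± 13 FPKM (1.38 ± 0.28, adjusted p = 0.00317). MDS (ISPF, PH02Gene03350) was also higher in leaf, at 34.8 ± 1.1 against 11.2 ± 2.9 FPKM (adjusted p = 0.00516). CMK (ISPE, MSTRG.14653) was at 29.4 ± 3.8 against 21.1 ± 3 FPKM (adjusted p = 0.0285), a call that ended without leaf library 1 (0.104) or 3 (0.0706), without stem library 1 (0.0598) or 2 (0.103) and without the filter. The DXS-step gene TKT2 (PH02Gene29284) was lower, at 15.5 ± 0.74 against 45.5 ± 8.7 FPKM (-1.47 ± 0.18, adjusted p = 0.000134). DXR (PH02Gene19646) and MCT (ISPD, PH02Gene10723) were not called, at 22.3 ± 0.62 against 41.1 ± 13 and 9.7 ± 2.2 against 6.7 ± 1.2 FPKM (adjusted p = 0.0599 and 0.101). DXR was called lower without stem library 1 (-0.86, adjusted p = 0.0133), with limma, after quantile normalization and with all 27 libraries, and MCT higher with DESeq2 and at a mean FPKM of 5 or more. Both were also called without stem library 1 and rhizome library 2. Of the mevalonate pathway, HMGR (PH02Gene07047) was higher in leaf, at 17 ± 1.3 against 5.62 ± 3.1 FPKM (1.70 ± 0.40, adjusted p = 0.00656). So was AACT (AAT1, PH02Gene24433), at 76.8 ± 6.9 against 42.6 ± 11 FPKM (0.94 ± 0.21, adjusted p = 0.00545). MVK (At5g27450, PH02Gene01687) was lower, at 8.31 ± 1 against 16.4 ± 2.3 FPKM (-0.89 ± 0.21, adjusted p = 0.00752). The GPPS-step gene SPS1 (PH02Gene03163), placed there by its KEGG number, was at 26.5 ± 0.68 against 11.1 ± 1.1 FPKM (1.35 ± 0.18, adjusted p = 0.000247). The isomerase IPI1 (PH02Gene44781) was at 123 ± 12 against 55.2 ± 10 FPKM (adjusted p = 0.0223). The IPI1 call ended without leaf library 2 (0.0626) or 3 (0.0556) and without stem library 2 (0.0611) or 3 (0.0628). Among the farnesyl pyrophosphate synthases, PH02Gene00438 was higher in leaf, at 214 ± 30.7 against 20.5 ± 18.5 FPKM (3.46 ± 0.69, adjusted p = 0.00267), and PH02Gene06534 lower, at 83 ± 12 against 214 ± 50 FPKM (-1.29 ± 0.21, adjusted p = 0.000865). Of 58 backbone genes 22 were higher and 7 lower (23 and 9 adjusted over the list alone), with no list call (median 0.20, adjusted p = 0.124). Of 47 carotenoid and abscisic acid genes 33 were higher and 6 lower (33 and 7 adjusted over the list alone). The median was 1.89 (adjusted p = 2.03e-11, and adjusted p = 0.384 with an estimated correlation). NCED1 (PH02Gene37228) was at 207 ± 68.4 against 0.323 ± 0.239 FPKM and NCED4 (PH02Gene08292) at 0.067 ± 0.0756 against 60.9 ± 46.2 FPKM. Of 67 light harvesting genes 57 were higher and 1 lower (60 and 1 adjusted over the list alone). The median was 2.53 (adjusted p = 5.94e-17, and adjusted p = 0.618 with an estimated correlation). Examples were CAP10A (PH02Gene43055), at 173 ± 50.5 against 6.2 ± 10.4 FPKM, and the single lower gene PSBR (PH02Gene09620), at 0.728 ± 1.1 against 77.7 ± 27.4 FPKM. Of 53 cuticle and wax genes 23 were higher and none lower, also when adjusted over the list alone. The median was 2.39, or 2.31 at the bound (adjusted p = 6.58e-06, and adjusted p = 0.629 with an estimated correlation). KCS12 (PH02Gene43832) was at 18.5 ± 0.657 against 0.023 ± 0.0398 FPKM.

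Of 95 starch and sucrose genes 38 were lower in leaf and 22 higher (42 and 26 adjusted over the list alone, median -0.54, adjusted p = 0.00814, and adjusted p = 0.473 with an estimated correlation). The amylose-forming granule-bound starch synthase WAXY (PH02Gene13019) was at 19.9 ± 9.76 against 4720 ± 1160 FPKM (-7.80 ± 1.66, adjusted p = 0.00382) and AGPL1 (PH02Gene27242) at 129 ± 15.6 against 1.51 ± 0.612 FPKM. The starch list call ended with limma (0.126, and 0.115 with 0.1 added), without the filter (0.0969), after quantile normalization and with all 27 libraries (0.0664), and without stem library 3 the median was -0.33 (adjusted p = 0.00673). Of 74 heat shock genes 40 were lower and 4 higher (41 and 4 adjusted over the list alone). The median was -1.77 (adjusted p = 0.000764, and adjusted p = 0.764 with an estimated correlation). HSP16.9C (PH02Gene22220) was at 22.4 ± 1.81 against 1560 ± 1160 FPKM and HSP70 (PH02Gene22640) at 72.6 ± 7.59 against 40.7 ± 2.75 FPKM (adjusted p = 0.0377). The HSP70 call ended without leaf library 1 (0.0721), 2 (0.0606) or 3 (0.117), without stem library 1 (0.0787), 2 (0.108) or 3 (0.0671), and with limma. Summed FPKM of the heat shock list was 40575 in stem library 1 against 12366 and 7663 in stem libraries 2 and 3, and without library 1 the median was -1.06 (adjusted p = 0.00885).

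Among the largest differences was that of the aquaporin PIP2-7 (PH02Gene05090), at 421 ± 123 FPKM in leaf and 0 in all stem libraries, at least 3140-fold higher (adjusted p = 3.13e-05). Carbonic anhydrase BCA2 (PH02Gene14703) was at 1390 ± 240 against 5.32 ± 0.583 FPKM, catalase-1 (OsI_09857, PH02Gene34256) at 3170 ± 348 against 16.1 ± 8.35 FPKM and algC (PH02Gene14975) at 188 ± 62.1 against 0.06 ± 0.0621 FPKM. Lower in leaf were CYP87A3 (PH02Gene31581), at 0.0897 ± 0.0991 against 189 ± 8.82 FPKM, and the flavonoid O-methyltransferase homologues PH02Gene44840, PH02Gene44839 and PH02Gene24615 (all Os11g0303600), at 2.54 ± 3.99, 1.7 ± 2.87 and 0.634 ± 0.999 FPKM against 856 ± 491, 394 ± 230 and 253 ± 146 FPKM. edgeR called 10843 of 29630 genes, 5198 higher and 5645 lower.

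The comparison of branch with the part-set stem called few genes. The wall-modifying XTH22 (PH02Gene05413) was higher in branch, at 112 ± 40.2 against 1.18 ± 1.44 FPKM (6.40 ± 1.22, adjusted p = 0.0418). So was the acid phosphatase APS1 (PH02Gene08196), at 56.9 ± 67.8 against 0.033 ± 0.0572 FPKM (10.29 ± 1.52, adjusted p = 0.0260). PHI-1 (PH02Gene06502) and the polyamine oxidase MPAO1 (PH02Gene05431) were at 0 in the 3 stem libraries and at 23 ± 5 and 24.5 ± 15 FPKM in branch, at least 155-fold (adjusted p = 0.0235) and at least 374-fold (adjusted p = 0.00679) higher. Also higher were Os01g0969100 (PH02Gene25759), at 25.8 ± 18.2 against 0.044 ± 0.0762 FPKM, the allene oxide synthase CYP74A2 (PH02Gene08787) of jasmonate synthesis, at 14.9 ± 3.71 against 0.167 ± 0.237 FPKM, SNL6 (PH02Gene33902), at 21 ± 1.34 against 4.13 ± 1.95 FPKM, and the wax synthesis gene CUT1 (PH02Gene34251), at 4.26 ± 2.35 against 0.026 ± 0.045 FPKM. The silicon efflux transporter LSI2 (PH02Gene46415) and the laccase LAC24 (PH02Gene33832) were at 0 in the stem libraries and at 4.91 ± 4.73 and 2.29 ± 2.54 FPKM in branch, at least 74.7-fold and at least 36.5-fold higher. Lower in branch were the aquaporin PIP2-1 (PH02Gene19725), at 107 ± 66.5 against 748 ± 256 FPKM (-2.95 ± 0.50, adjusted p = 0.0386), M3KE1 (PH02Gene39519), at 22.8 ± 9.54 against 144 ± 37.6 FPKM (-2.78 ± 0.31, adjusted p = 0.00782), COL15 (PH02Gene08634), at 10.8 ± 4.3 against 84.9 ± 24.3 FPKM, the polygalacturonase PH02Gene31815, at 1.44 ± 0.328 against 20.1 ± 16.9 FPKM, CYP96A15 (PH02Gene24894), at 2.59 ± 0.476 against 20.3 ± 14.6 FPKM, and the expansin-like EXLA1 (PH02Gene34262), at 26.1 ± 4.83 against 101 ± 35.6 FPKM. Of these 16 genes 15, all but MPAO1, lost the call without at least 1 library. Without branch library 1, 2 or 3, 12, 12 and 13 did, with adjusted p of 0.0564 to 0.0970, 0.0608 to 0.140 and 0.0593 to 0.120. Without stem library 1, 2 or 3, 13, 15 and 5 did, with adjusted p of 0.0597 to 0.125, 0.0510 to 0.164 and 0.0532 to 0.0730.

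No terpene synthase (0 of 23, 1 higher adjusted over the list alone) and no backbone gene (0 of 58, also over the list alone) was called by edgeR. TPS2 (PH02Gene40249) was at 24.4 ± 13 FPKM in branch and 48.1 ± 19.9 FPKM in stem (adjusted p = 0.262), MSTRG.59063 at 27.7 ± 13 and 60.1 ± 19 FPKM (0.162), FPS (PH02Gene06534) at 147 ± 3.3 and 214 ± 50 FPKM (0.139) and TPS7 (PH02Gene09155) at 8.7 ± 6.1 and 22.1 ± 36 FPKM (0.680). The medians were -0.93 (adjusted p = 0.230) and 0.04 (adjusted p = 0.899), the backbone test pointing lower against the sign of its median. The synthase list was called lower without branch library 3 (median -1.04, adjusted p = 0.0162) or stem library 1 (-1.21, 0.00650).

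The cuticle and wax list was called higher in branch (4 of 53 genes higher, 24 adjusted over the list alone, median 2.09, or 1.77 at the bound, adjusted p = 1.73e-19, and adjusted p = 0.384 with an estimated correlation). So were the lists of wall expansion genes (3 of 55 higher and 2 lower, 22 and 2 adjusted over the list alone, median 1.27, adjusted p = 8.61e-09, and adjusted p = 0.558 with an estimated correlation) and jasmonate genes (2 of 60, also adjusted over the list alone, median 0.78, adjusted p = 1.14e-06, and adjusted p = 0.629 with an estimated correlation). The lists of defence genes (0 of 53, 9 adjusted over the list alone, median 0.98, or 0.94 at the bound, adjusted p = 6.26e-06, and adjusted p = 0.384 with an estimated correlation), lignin genes (1 of 134, also adjusted over the list alone, median 0.43, adjusted p = 0.000186, and adjusted p = 0.629 with an estimated correlation) and flavonoid genes (1 of 48, 2 adjusted over the list alone, median 0.21, adjusted p = 0.0273, and adjusted p = 0.629 with an estimated correlation) were also called higher. The heat shock list (0 of 74 genes called, 3 lower and 1 higher adjusted over the list alone, median -0.79, adjusted p = 3.57e-06, and adjusted p = 0.647 with an estimated correlation) was called lower, with summed FPKM of 40575, 12366 and 7663 in stem libraries 1, 2 and 3 and 8695 to 10274 in branch, and the call ended without stem library 1 (-0.21, 0.194). The light harvesting list (0 of 67 genes called, also adjusted over the list alone, median -0.56, adjusted p = 0.00144, and adjusted p = 0.842 with an estimated correlation) was called lower, a call that ended without branch library 2 (-0.46, 0.0590), after quantile normalization, and without stem library 1, where the test pointed higher (median -0.12, adjusted p = 0.865). The flavonoid call ended without branch library 1 (0.0944) or stem library 1 (0.0931), with limma, at a mean FPKM of 5 or more and with all 27 libraries, and its median was 0.35 without branch library 3 (adjusted p = 0.0414). Without stem library 3 the medians of wall expansion, jasmonate, defence, lignin and flavonoid genes were 2.30, 1.32, 1.80, 0.76 and 0.61 (adjusted p = 2.81e-08, 2.21e-11, 3.46e-06, 7.81e-05 and 0.0313). That of jasmonate genes was 0.51 without stem library 1 (1.79e-05) and that of lignin genes 0.24 without stem library 2 (0.0137).

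In all 234 genes were called, 145 higher (62.0%) and 89 lower. With limma on log2(FPKM + 1), where the median change of all genes was 0.11, 797 (86.3%) were higher and 127 lower. Without branch library 1, 2 or 3 edgeR called 95, 18 and 18 genes, and without stem library 1 or 2 it called 56 and 2. The calls of LAC24 (PH02Gene33832) and LSI2 (PH02Gene46415) ended after quantile normalization, with only the 2 groups in the fit, and without stem library 1 and rhizome library 2. Without those libraries the call of Os01g0969100 (PH02Gene25759) ended too, with limma on log2(FPKM + 1) that of LAC24 ended, and with all 27 libraries in the fit that of EXLA1 (PH02Gene34262) did. FPS (PH02Gene06534) was called with DESeq2.

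In rhizome against the part-set stem, TPS2 (PH02Gene40249) was at 8.88 ± 1.5 against 48.1 ± 19.9 FPKM (-2.47 ± 0.47, adjusted p = 0.00367) and the alpha-terpineol synthase homologue TPS10 (MSTRG.17598) at 0.252 ± 0.233 against 27.3 ± 19.2 FPKM (-6.66 ± 1.18, adjusted p = 0.00385). TPS26 (PH02Gene44577) was at 0 in all rhizome libraries, at least 23.6-fold lower (adjusted p = 0.0131), a call that ended with limma on log2(FPKM + 1), quantile normalization, only the 2 groups in the fit, or without stem library 1 and rhizome library 2. Of 23 terpene synthases 10 were lower and none higher, also when adjusted over the list alone. The median was -2.13 (adjusted p = 0.000559, and adjusted p = 0.647 with an estimated correlation). The list call ended without the expression filter (0.0658), and without stem library 3 the median was -1.17 (adjusted p = 0.0147). Among precursor genes, FPS (PH02Gene06534) was at 62.6 ± 3.6 against 214 ± 50 FPKM (-1.83 ± 0.22, adjusted p = 0.000254), GGPS (PH02Gene17903) at 6.6 ± 0.51 against 37 ± 10 FPKM (-2.52 ± 0.28, adjusted p = 0.000159) and the FPS gene PH02Gene40477 at 0.74 ± 0.651 against 15.6 ± 3.17 FPKM. The isomerase IPI1 (PH02Gene44781) was higher, at 173 ± 93 against 55.2 ± 10 FPKM (1.63 ± 0.37, adjusted p = 0.00867). So was the FPS gene PH02Gene38408, at 19 ± 19.9 against 0.0287 ± 0.0497 FPKM (8.89 ± 1.96, adjusted p = 0.00727). Both calls ended with only the 2 groups in the fit, that of PH02Gene38408 also with limma on log2(FPKM + 0.1) (0.0508). Of the most abundant gene of each step, 1 of 6 in the mevalonate pathway was higher and 1 lower, and 1 of 7 in the plastid pathway was higher and 2 were lower. Of 58 backbone genes 17 were lower and 8 higher (17 and 11 adjusted over the list alone), with no list call (median -0.25, adjusted p = 0.113). Without stem library 2 the backbone list was called lower (-0.33, adjusted p = 0.0366).

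Of 67 light harvesting genes 60 were lower and 1 higher (61 and 1 adjusted over the list alone). The median was -6.93 (adjusted p = 7.78e-68, and adjusted p = 0.384 with an estimated correlation). CAB8 (PH02Gene45771) was at 1.43 ± 1.32 against 651 ± 298 FPKM (-8.85 ± 0.76, adjusted p = 3.37e-05), CAB1 (PH02Gene35533) at 0.51 ± 0.23 against 464 ± 440 FPKM and, outside the list, the early light-inducible ELIP1 (PH02Gene44636) at 0.623 ± 0.507 against 315 ± 96.4 FPKM and PSBS2 (PH02Gene34222) at 0.359 ± 0.42 against 295 ± 161 FPKM. At4g08330 (PH02Gene19244) was the member that was higher, at 21.5 ± 8.57 against 4.58 ± 2.51 FPKM, a call that ended with only the 2 groups in the fit. Carotenoid genes were lower in 23 of 47 and higher in none (26 and 1 adjusted over the list alone). The median was -1.31, or -1.20 at the bound (adjusted p = 8.66e-08, and adjusted p = 0.481 with an estimated correlation). The phytoene synthase PSY1 (PH02Gene29430) was at 0.455 ± 0.195 against 31.5 ± 11.4 FPKM. Triterpene and sterol genes were lower in 6 of 20 and higher in none (8 and 0 adjusted over the list alone). The median was -1.06 (adjusted p = 0.0146, and adjusted p = 0.638 with an estimated correlation), a call that ended without the filter (0.0964) and at a mean FPKM of 5 or more (0.0534). An achilleol B synthase homologue (Os11g0285000, PH02Gene49482) was at 7.68 ± 3.67 against 59.3 ± 39.5 FPKM. Flavonoid genes were lower in 17 of 48 and higher in 5 (17 and 7 adjusted over the list alone). The median was -0.59 (adjusted p = 0.00328, and adjusted p = 0.523 with an estimated correlation). That call ended without rhizome library 2 (-0.80, 0.0811) and with all 27 libraries in the fit (0.0575), and without rhizome library 3 the median was -1.09 (adjusted p = 0.00397). At3g11180 (PH02Gene04930) was at 0.279 ± 0.355 against 50.1 ± 69 FPKM, and the flavonoid 3'-hydroxylase CYP75B4 (PH02Gene41827) at 20.7 ± 21.2 against 0.653 ± 0.477 FPKM (adjusted p = 0.0175), a call that ended without stem library 2 (0.0630) or 3 (0.0534), without stem library 1 and rhizome library 2 together (0.0566) and with only the 2 groups in the fit.

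Of 74 heat shock genes 43 were lower and 3 higher (44 and 6 adjusted over the list alone). The median was -1.82 (adjusted p = 3.58e-06, and adjusted p = 0.647 with an estimated correlation). Without stem library 1, whose summed heat shock FPKM was 40575, the median was -1.13 (adjusted p = 7.08e-06). HSP24.1 (PH02Gene06505) was at 0.32 ± 0.134 against 329 ± 412 FPKM and HSC-I (PH02Gene06078) at 71.9 ± 3.99 against 8.03 ± 1.39 FPKM. Higher in rhizome were also the starch-degrading beta-amylase BMY1 (PH02Gene08694), at 1090 ± 1080 against 8.72 ± 1.34 FPKM (6.99 ± 1.03, adjusted p = 0.000905), the glutathione transferase GSTF1 (PH02Gene33265), at 62.7 ± 3.63 against 0.818 ± 0.395 FPKM (6.19 ± 0.51, adjusted p = 2.45e-05), OPR5 (PH02Gene25747), at 78 ± 76.4 against 0.0763 ± 0.132 FPKM, At5g07050 (PH02Gene04538), at 46.1 ± 36.8 against 0.159 ± 0.216 FPKM, and CYP709B2 (PH02Gene07726), at 35.1 ± 16.3 against 0.284 ± 0.188 FPKM. The flavonoid O-methyltransferase homologue PH02Gene44840 was at 0.787 ± 0.505 against 856 ± 491 FPKM.

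edgeR called 8762 genes, 4303 higher and 4459 lower, and 5464 without rhizome library 1, whose values lay between those of rhizome libraries 2 and 3. With only the 2 groups in the fit 3569 were called. The lists of gibberellin and labdane diterpenoid genes, of CYP71, CYP76, CYP99 and CYP701 cytochromes P450 and of root endodermis and silicon uptake were called in none of the 8 comparisons, and in rhizome 7 of 36, 5 of 31 and 11 of 48 of their genes were higher and 9, 5 and 10 lower (8, 5 and 12 higher and 9, 5 and 11 lower adjusted over each list alone), with medians of 0.20, 0.07 and 0.03 (adjusted p = 0.899, 0.899 and 0.777) and tests that pointed lower. The root list was called higher in the 0.5-year stem with limma and after quantile normalization, and lower in leaf at a mean FPKM of 5 or more and with only the 2 groups in the fit.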

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

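Of the counts of called genes and the backbone and terpene synthase medians, 353 values under an alternative kept their side of the threshold or stayed within 1.5 times, 48 counts moved further, 22 list calls ended and 8 were gained, and no called test turned its direction. Medians turned sign for the leaf synthases without the filter, for the backbone (3 against 2 years, branch) and for the synthases (3 against 2 years) with 1 library left out. The cause of the changes below was not tested, except where fewer genes or libraries entered the fit. Limma on log2(FPKM + 1), the summed 0.5-year libraries and the paired omissions were chosen after seeing the data. The lone summed sample is assumed to vary like the other groups.

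With a mean FPKM of 5 or more, where fewer genes were tested, 10038 genes were called for the 0.5-year stem against the shoot, 8653 for 3 years against 0.5 years and 140 for branch. With the 0.5-year libraries summed to 1 sample, 9418, 2137, 1, 0 and 6690 were called for the 0.5-year stem against the shoot, 1 against 0.5, 2 against 1, 3 against 2 and 3 against 0.5 years. For 2 against 1 year, limma on log2(FPKM + 1) called 816 genes, only the 2 groups 110, DESeq2 1788, all 27 libraries 60, and leaving out shoot 3 and 1-year 1 gave 1026. For 3 against 2 years these were 7, 0, 91, 0 and 5, with 4 for limma on log2(FPKM + 0.1), 7 after quantile normalization and 1 with RLE factors. For branch, limma called 924 and, with 0.1 added, 593, quantile normalization 638, only the 2 groups 472, DESeq2 1828, all 27 libraries 1888, and leaving out part-set stem 1 and rhizome 2 gave 373. For rhizome, only the 2 groups gave 3569. With 1 library left out the counts ranged from 15 to 1047 for 2 against 1 year, 0 to 2 for 3 against 2 years, 2 to 306 for branch and 5464 to 10235 for rhizome. After quantile normalization the share of calls that were higher went from 47.5% to 53.2% for 1 against 0.5 years, 47% to 53% for 3 against 0.5 years, 47.9% to 51.3% for leaf and 49.1% to 54.7% for rhizome.

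With an estimated correlation the terpene synthase medians were the same but no call was left: 3.04 (0.5-year stem against shoot), -0.44 (1 against 0.5 years), -1.02 (2 against 1 year), -2.13 (3 against 0.5 years), -6.18 (leaf) and -2.13 (rhizome), with adjusted p from 0.647 to 0.821. For 1 against 0.5 years the call ended without the filter (-0.31) and with all 27 libraries (-1.11). For 2 against 1 year it ended with limma (-0.68, and -1.13 with 0.1 added), without the filter (-0.61), at a mean FPKM of 5 or more (-0.70) and with all 27 libraries (-0.62), and the median ranged from -1.39 to -0.47 with 1 library left out. For leaf it ended with limma (-1.36), without the filter (0.13, the test still pointing lower) and with all 27 libraries (-4.05), and for rhizome without the filter (-1.08). The branch list was called lower with limma (-0.39), at a mean FPKM of 5 or more (-1.02) and without part-set stem 1 and rhizome 2 (-1.16), and ranged from -1.21 to -0.18 with 1 library left out. The backbone was called higher in the 0.5-year stem without the filter (0.47). With 1 library left out its median ranged from -0.029 to 0.286 for 3 against 2 years and from -0.45 to -0.17 for rhizome. For the 15 other lists, 693 values stayed, 13 calls ended and 13 were gained with 1 library left out, and 1083, 40 and 30 did under the settings other than the block and the estimated correlation. Tests turned for light harvesting in branch without part-set stem 1 (-0.12, the range with 1 library left out being -0.79 to -0.12) and, at a mean FPKM of 5 or more, for cuticle and wax in 1 against 0.5 years (0.70) and 3 against 2 years (0.64, then called, adjusted p = 0.0432).

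Libraries with the same replicate number did not deviate together in every pair, so the numbers were not used to pair them. As the check needs every pair, it cannot exclude a pairing or batch in some comparisons. A replicate block gave 15859, 9022, 463, 0 and 13495 calls in the growth stage comparisons in the order above, and 9863, 7244 and 24 for leaf, rhizome and branch. With it the terpene synthase call ended for 1 against 0.5 years (-0.55) and 2 against 1 year (-0.86) and the wall expansion call for 3 against 2 years (-0.12, adjusted p = 0.0572), and 43 of the 46 list calls were kept. Libraries correlated best with their own number in 2, 1, 1, 3 and 2 of 3 cases in the growth stage comparisons and in 0, 2 and 1 for leaf, branch and rhizome.

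For the 174 results on named genes, 1885 values under other settings kept their side of the threshold, 85 calls ended and 18 were gained, and none reversed. The replicate block ended 20 calls, 13 of them in branch, the summed 0.5-year libraries 21 and only the 2 groups 12. With 1 library left out, 896 stayed, 144 calls ended and 4 were gained. Depth limits the low genes, since 3 counts amount to 0.242 to 0.479 CPM.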

Other observations

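The transcription factor families, the aliquot test and the branch value of the heat shock test were chosen after the values were seen, and the tests of the rhizome mixture and of part-set stem library 1 had their outcomes written down before. Families of transcription factors are those the tables assign. In the 0.5-year stem against the shoot, 84 of 133 AP2-EREBP genes rose and 14 fell, with a median log2 change of 2.33 (camera, adjusted p = 5.89e-13, and adjusted p = 0.0587 with an estimated correlation). Of 28 Tify genes 23 rose and 2 fell (median 4.99, adjusted p = 7.34e-11, and adjusted p = 0.530 with an estimated correlation), and of 110 WRKY genes 77 rose and 9 fell (median 2.28, adjusted p = 3.08e-10, and adjusted p = 0.660 with an estimated correlation). Growth-regulating factors fell in 15 of 19 and rose in 1 (median -3.58, adjusted p = 8.45e-07, and adjusted p = 0.618 with an estimated correlation). In the 3-year against the 0.5-year stem, 50 of 111 NAC genes rose and 20 fell (median 0.81, adjusted p = 3.23e-05, and adjusted p = 0.680 with an estimated correlation). In leaf against the part-set stem, 59 of 123 AP2-EREBP genes were lower and 9 higher (median -2.39, adjusted p = 8.45e-07, and adjusted p = 0.660 with an estimated correlation), and 17 of 37 MADS genes were lower and 2 higher (median -1.48, adjusted p = 0.000250, and adjusted p = 0.112 with an estimated correlation). Of 222 tests of families 39 were called, and none with an estimated correlation.

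Rhizome library 1 lay between libraries 2 and 3, and may hold a mixture of RNA like theirs. Read from 864 and 926 genes nearly private to each, the shares of libraries 2 and 3 in it were 0.434 and 0.553. Their sum was 0.987 (bootstrap 0.978 to 0.996), inside the range written down beforehand for a mixture but just under 1. A linear mixture came within 1.5-fold for 92.4% of 4237 genes, against 32% for the geometric mean. The shares came from library 1, so this is no independent test. In library 1, 0.0882% of genes lay over 2-fold above both others (7% and 2.69% in libraries 2 and 3). Tissue lying between the others stays open, and no biological explanation was tested.

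The heat shock list was called lower in leaf (adjusted p = 0.000764, and adjusted p = 0.764 with an estimated correlation) and rhizome (adjusted p = 3.58e-06, and adjusted p = 0.647 with an estimated correlation) than in the part-set stem, and part-set stem library 1 stood highest. That this single library, possibly heat-stressed, is the whole cause was argued against, since without it at least 59.9% of the median change remained in leaf and rhizome. Against branch, where the call ended without it and 26% remained (median -0.21, adjusted p = 0.194), this stays open. A part of the difference may still come from it, and a difference between the parts stays open.

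The 3 libraries of the 0.5-year stem were closer to each other than those of any other group. The lowest chi-square per degree of freedom, 1.78, is above sampling noise, but library preparation adds spread. Aliquots of 1 RNA pool thus cannot be told apart from separate, closely matched stems.

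Other splits of the 6 libraries of each comparison into 3 and 3 were run through the same edgeR test. In every comparison 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real split gave 15891, 8981, 443, 2 and 13531 genes in the growth stage comparisons and 10843, 234 and 8762 for leaf, branch and rhizome. The highest other split gave 90 for 2 against 1 year, 15 for branch and 0 for each of the others.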
